A study of Caenorhabditis elegans with 4 samples.

How the data were processed

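Binding of the transcription factor UNC-62 was mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in Caenorhabditis elegans embryos of the strain OP600. This strain carries a transgene in which unc-62, a homeodomain gene of the MEIS/Homothorax class, is fused to EGFP and FLAG tags, together with unc-119, which marks animals that hold the transgene. Per the labels' protocols, worms were raised at 20 °C, crosslinked with 2% formaldehyde and sonicated, and tagged protein was collected with anti-GFP antibodies. Part of each lysate was kept as input DNA. The 4 samples form 2 groups, UNC-62 ChIP with 2 replicates and Input with 2 replicates. No processed file of the Input samples was used here, so the input enters only as far as the authors' peak calling used it.

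The data are 3 lists of binding regions, 1 for each ChIP replicate and 1 for the whole series. Per the file headers, coordinates are on the WormBase WS220 genome build. The regions were called with PeakSeq, per the source column of the deposited files. PeakSeq scores regions of enriched reads in the ChIP library against a control library. The version of PeakSeq, the aligner, the read filters and the way the series list was made from the replicates are not given in the sources used here. Whether the replicates came from separate cultures is not stated either.

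Each region has a start, an end and 1 value, deposited by the authors without a name. It was treated as a q-value, the unit in which the deposited p-value has been corrected for the number of regions. The basis for this is a product, the value multiplied by the number in the region's name. It never decreased along those numbers (0 decreases in each of the 3 lists). A p-value multiplied by the number of regions and divided by its rank behaves in this way. Any value that rises along those numbers does so too, so the check does not tell a q-value from a p-value. The reading as a q-value is therefore an assumption. The largest value was 0.00999 in the replicate 1 list, 0.000998 in the replicate 2 list and 0.000997 in the series list, so the replicate 1 list reached a limit about 10 times looser. Of the numbers used in region names, 38 are absent from the series list, 47 from the replicate 1 list and 11 from the replicate 2 list, and the lowest absent number is 4506, 4619 and 2366. The strongest regions of each list are therefore numbered without gaps. The lists hold no read counts, so the depth of the libraries is unknown and no value here carries an error from read counting. The smaller a q-value, the stronger a region is called below. q-values depend on depth as well as on enrichment, so strength was ranked only within a list. Where the q-values of a region in 2 lists are set side by side, the difference reflects depth and enrichment together and does not measure binding.

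Regions of 2 lists were called shared when they overlapped by at least 1 bp. The overlap expected by chance came from 10000 random placements, in which all regions of replicate 2 on a chromosome were shifted by 1 random distance around the chromosome, with a one-sided permutation p. The q-values of shared regions were compared on the −log10 scale by Spearman and Pearson correlation with two-sided permutation p from 100000 resamples. A q-value listed as 0 took the smallest value above 0 in its list, and each replicate 2 region was paired with its strongest partner. Intervals of shares are exact 95% Clopper-Pearson intervals over regions, which treat regions as independent.

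Chromosome lengths of WS220 were not used. The length of a chromosome was taken as the highest region end on it in any of the 3 lists, which sums to 100.1 Mb over 6 chromosomes. Numbers of regions per chromosome were compared with those expected from length by two-sided exact binomial tests, and the share of region midpoints in the central 50% of each chromosome was tested against 50% in the same way. Both sets of 6 tests were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Because regions lie in clusters, 95% intervals were also computed by resampling 500 kb blocks 10000 times.

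The rule for the regions named was fixed before the data were examined, as were the tests of overlap, of q-value correlation, of numbers per chromosome and of central shares. The comparison of X with the autosomes, the block intervals and the dense blocks were added afterwards. The regions named are the 10 strongest of the series list and the 5 strongest of each replicate list with no match in the other replicate. The planned assignment of regions to promoters, gene lists and exons, the motif counts and the count of regions near unc-62 and unc-119 were not run. The gene table at hand is on the WBcel235 assembly, a different build from the regions, and was used only to look up the chromosome of a gene by name. Regions are therefore named by position and carry no gene annotation.

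The overlap, chromosome and midpoint tests were tested on simulated lists of the real sizes. With 40% of 3138 regions copied from a list of 7782, the overlap found was 42.6% against 5.18% by chance. Of 100 pairs of unrelated lists, 3% fell under p = 0.05 in the permutation test. For the chromosome comparison of 7964 regions, a chromosome V at 0.7 times the density of the others was called in 100 of 100 simulated lists. Without any preference, 4.67% of the exact midpoint tests fell under 0.05 and 8.17% of the block intervals left out a ratio of 1, so those intervals are somewhat narrow. The planted density of 0.7 is a large difference for this many regions, so its recovery says little about smaller ones. The simulations used fewer random placements and block resamples than the real lists did. The simulated regions were placed independently and uniformly along a chromosome, apart from the copied ones. They lack the clusters of the real lists, so these rates need not hold for the real lists. The alternatives covered the definition of overlap, the q-value limit, equal list lengths, other random placements, each replicate's list in place of the series list, other definitions of the chromosome centre, and merging of regions under 2 kb apart. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.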

Results

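UNC-62 binding regions were available for 2 ChIP replicates of embryos and as a list for the whole series. The replicate 1 list held 7782 regions covering 2.49 Mb, the replicate 2 list 3138 regions covering 1.17 Mb, and the series list 7964 regions covering 2.92 Mb, or 2.92% of the 100.1 Mb spanned. Regions were narrow. Their median width was 275 bp in replicate 1, with quartiles of 189 and 393 bp, 320 bp in replicate 2, with quartiles of 242 and 435 bp, and 312 bp in the series list. A small number were under 20 bp wide, namely 216 in replicate 1, 25 in replicate 2 and 130 in the series list. The depth of the libraries is unknown, since the lists give no read counts.

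The first question was whether the replicates marked the same places. Nearly all regions of replicate 2 were found in replicate 1, whereas most regions of replicate 1 had no counterpart in replicate 2. Of the 3138 replicate 2 regions, 2976 overlapped a replicate 1 region (94.8%, 95% interval 94.0 to 95.6%). Of the 7782 replicate 1 regions, 2949 overlapped a replicate 2 region (37.9%, 95% interval 36.8 to 39.0%). Shifted at random along their chromosomes, replicate 2 regions met replicate 1 regions in 5.48% of cases on average and in 19.9% at most, so the observed overlap lay above all 10000 placements (one-sided permutation p = 1e-04, the smallest these placements can give). The asymmetry was accompanied by a difference in the limits of the lists. Held to q-values under 0.001, replicate 1 kept 5697 regions, 1.82 times the number in replicate 2 in place of 2.48 times, and 50.1% of them were shared. With the 3138 strongest regions of each list, 76.1% of replicate 1 and 77.4% of replicate 2 were shared; equal list lengths make these shares close by construction.

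Sharing followed strength. With each list sorted by q-value and cut into 10 steps of equal size, all 779 regions in the strongest step of replicate 1 were shared. The shared percentage was 91.1% in step 2, 26.2% in step 5 and 2.57% in step 10, the weakest. The overlap by chance was computed for replicate 2 regions only. Whether the weakest steps of replicate 1 were shared more often than by chance was therefore not tested. In replicate 2 it was 100% in the strongest step and 78.9% in the weakest. Regions of replicate 1 without a counterpart were weaker and narrower than shared ones, with a median q-value of 0.00051 against 2.64e-11 and a median width of 219 against 384 bp. The 162 regions found only in replicate 2 had a median q-value of 0.000391 and a median width of 137 bp.

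**Figure D1:**
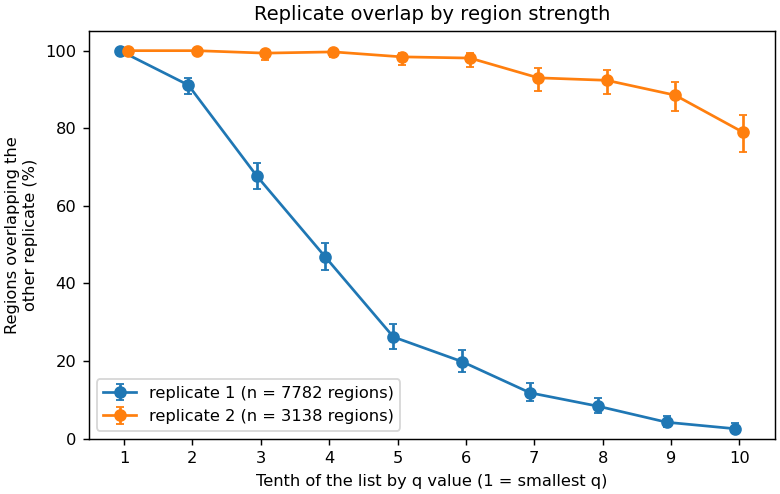
Percentage of regions (y axis) that overlapped the other replicate by at least 1 bp, for each of 10 equal steps of a replicate's list ordered by q-value (x axis, 1 = smallest q-values). Points are percentages and bars exact 95% binomial intervals over regions; replicate 1 falls from 100% to 2.57%, replicate 2 from 100% to 78.9%.

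The order of strength was also shared. Over the 2976 pairs of overlapping regions, the −log10 q-values of the replicates correlated with a Spearman rho of 0.75 and a Pearson r of 0.86 (permutation p = 1e-05 for each, the smallest that 100000 resamples can give). This correlation is across regions, which are not independent replicates, and only regions present in both lists enter it. The q-value, which reflects depth and enrichment together, was smaller in replicate 1 in 2665 of the 2976 pairs (89.5%, 95% interval 88.4 to 90.6%).

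The series list was then set against the replicate lists, because all location results rest on it. Of its 7964 regions, 2923 overlapped a region in both replicates (36.7%, 95% interval 35.6 to 37.8%), 3813 in replicate 1 only (47.9%), 99 in replicate 2 only (1.24%) and 1129 in neither (14.2%). The regions supported by both replicates were the strongest and widest, with a median q-value of 1.21e-17 and a median width of 435 bp. Those in replicate 1 only had a median q-value of 3.39e-06 and those in neither 0.000233. Where a series region matched a replicate region, its q-value was the smaller one in 97.6% of 6736 matches with replicate 1 and in 99.3% of 3022 matches with replicate 2. A series region overlapped 87.6% of the replicate 1 regions and 98.2% of the replicate 2 regions. These shares compare unlike limits, as q-values reached 0.00999 in replicate 1 but only 0.000997 in the series list. With all lists under 0.001, 33.8% of series regions were in replicate 1 only and 28.3% in neither. Of the 2844 replicate 1 regions under 0.001 without a match in replicate 2, 2721 overlapped a series region. No list of the Input samples was used, so there is no test between groups of samples, and the p-values in this section describe these lists.

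The 10 strongest regions of the series list lay on all 6 chromosomes, and each was found in both replicates. A q-value of 0 was listed for 2 of them, IV 14032402 to 14034890 (2489 bp) and V 4498493 to 4511955 (13463 bp). The chromosome IV region had q-values of 1.44e-247 in replicate 1 and 4.19e-120 in replicate 2. The chromosome V region had a listed q-value of 0 in replicate 1 and was covered by 2 regions in replicate 2, the stronger with a q-value of 4.12e-173, the smallest in that list. Next came IV 13695430 to 13696438 (1009 bp), with 1.16e-295 in the series list, followed by II 11633726 to 11636187 (2462 bp) with 1.79e-221 and III 12612224 to 12614039 (1816 bp) with 3.89e-203. A further region on V, from 4490593 to 4492096 (1504 bp), had a q-value of 1.9e-181. It was followed by I 7711507 to 7715158 (3652 bp) with 1.71e-179 and X 16929335 to 16931961 (2627 bp) with 1.54e-178. The last 2 were III 6978615 to 6979450 (836 bp) with 1.49e-175 and III 8416821 to 8417983 (1163 bp) with 1.4e-172.

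The strongest regions that only 1 replicate contained ranked lower in the series list. The series regions they overlapped had q-values of 1.09e-19 to 1.17e-12 for the 5 from replicate 1 and of 1.86e-16 to 0.000165 for the 5 from replicate 2. With q-values from their own list, those of replicate 1 were IV 2998404 to 2999449 (q-value 2.85e-17), IV 1857848 to 1858418 (3.33e-17), III 3543107 to 3543581 (1.96e-16), X 7224387 to 7225377 (1.94e-15) and X 3456698 to 3457168 (2.58e-15). Of those of replicate 2, the first 2 were neighbours on X, from 16375085 to 16375654 (2.6e-10) and from 16373067 to 16373852 (2.38e-09). The other 3 were IV 7632583 to 7632867 (2.48e-07), III 7183996 to 7184182 (1.71e-06) and II 9310709 to 9311025 (1.86e-06).

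The chromosomes differed in their density of regions. Chromosome V carried the fewest, 54.9 regions per Mb, and chromosome III the most by number, 97.7 per Mb. By covered base pairs X ranked first, at 1.22 times the value expected from length (interval from resampled blocks 1.102 to 1.33). Next were I at 1.15 (interval 1.007 to 1.28) and III at 1.12 (interval 0.981 to 1.27, which includes 1). Relative to the number expected from length, V held 1149 regions against 1664 (ratio 0.69, 95% interval from resampled blocks 0.597 to 0.787; exact binomial adjusted p = 6.65e-49). Chromosome III held 1347 against 1096 (ratio 1.23, interval 1.09 to 1.37; exact binomial adjusted p = 7.58e-15). Chromosome I was also above expectation, at a ratio of 1.17 (interval 1.05 to 1.29; exact binomial adjusted p = 8.89e-10), as was X at 1.09 (interval 1.001 to 1.18; adjusted p = 0.000169). Every expected value was taken over all chromosomes, V included, so the low number on V raises the ratios of the others. By regions per Mb X ranked below III and I. Whether X, I or III would exceed an expectation that leaves out V was not tested. Chromosome IV was below it at 0.91 (interval 0.823 to 0.994; exact binomial adjusted p = 0.000169), and II did not differ from it past the threshold at 1.05 (interval 0.908 to 1.18; adjusted p = 0.0707). In the replicate 2 list alone the ratios of I (1.02, exact binomial adjusted p = 0.689) and IV (0.964, adjusted p = 0.431) no longer passed, and that of II did (1.099, adjusted p = 0.0294). In the replicate 1 list alone, II passed as well, at 1.08 (exact binomial adjusted p = 0.00372). The block intervals gave fewer calls. They included 1 for II in the replicate 1 list (0.938 to 1.22) and the replicate 2 list (0.896 to 1.296), and in the replicate 1 list also for I (0.988 to 1.22) and IV (0.839 to 1.01). In the series list with regions under 2 kb apart merged, the interval of IV included 1 too (0.859 to 1.014). Against the expectation that includes V, the chromosomes V, III and X kept their direction and their call in either replicate's list. With replicate 2 first, the ratios were 0.621 and 0.71 for V, 1.24 and 1.21 for III, and 1.2 and 1.1 for X. The ratios of III and X are raised by the low number on V in these lists too, so they are not separate from it. The exact tests count neighbouring regions as independent, which the block intervals do not.

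**Figure D2:**
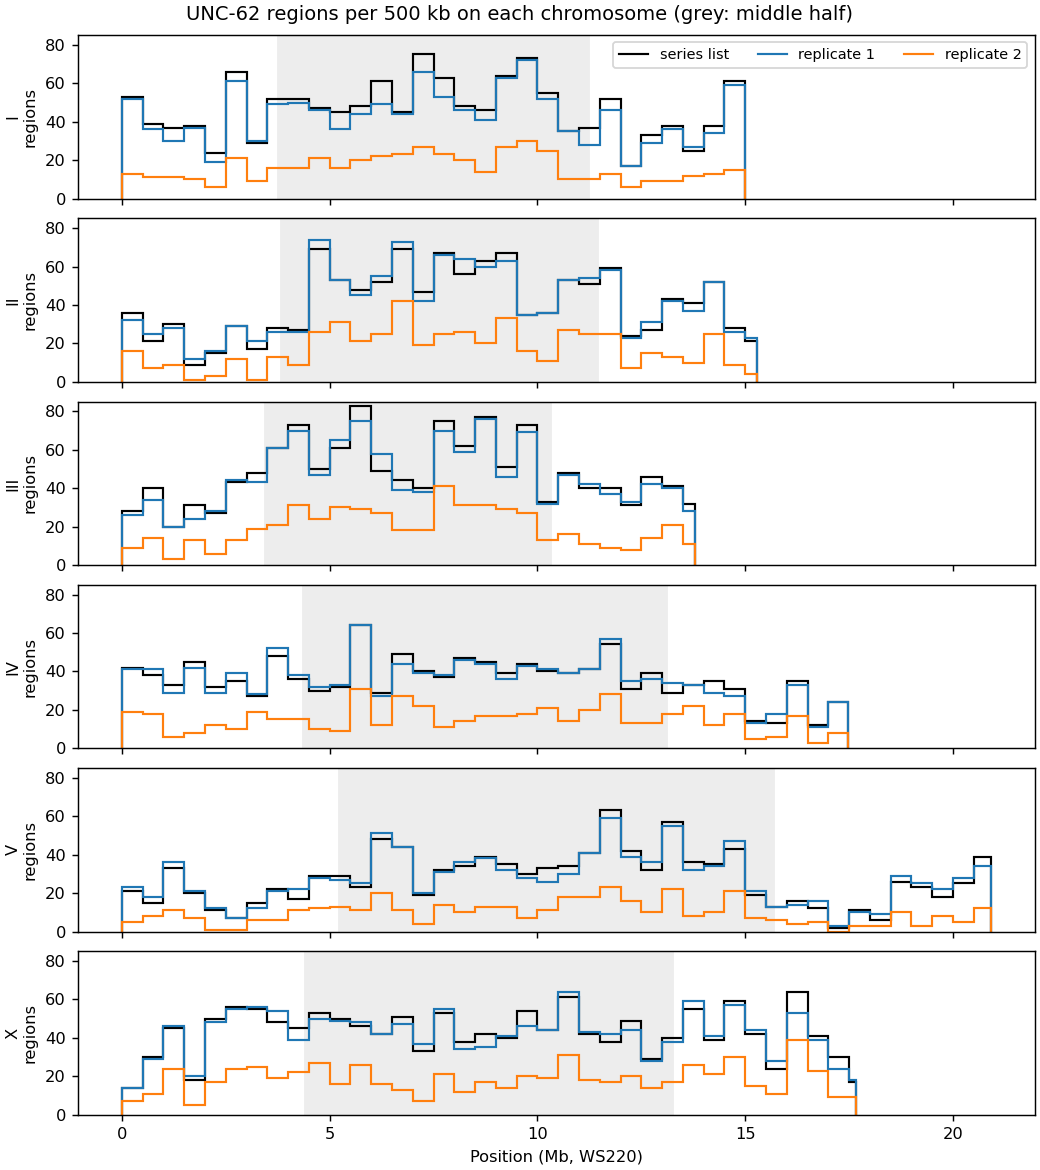
Number of UNC-62 regions per 500 kb (y axis) along each chromosome (x axis, Mb on WS220) in the series list, replicate 1 and replicate 2; grey marks the central 50% of each chromosome. Chromosome V has the lowest density in the series list, and the grey part holds 57.5% to 66.9% of the regions of each autosome and 51.98% of those of X.

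On every autosome the regions were concentrated in the central 50% of the length, and on X the share there did not pass the test. This central part held 66.9% of the regions of V (exact 95% interval 64.1 to 69.6%), 62.9% on II (60.2 to 65.6%), 61.2% on III (58.6 to 63.9%), 59.0% on I (56.3 to 61.5%) and 57.5% on IV (54.7 to 60.3%). Each of these 5 shares differed from 50% (exact binomial test, largest adjusted p = 1.18e-07). On X the share was 51.98% (49.5 to 54.5%; exact binomial adjusted p = 0.126). The difference between X and the autosomes, tested after these shares were seen, was itself beyond the spread between blocks. X lay 9.38 percentage points below the pooled autosomal share of 61.4% (difference -9.38, 95% interval from resampled blocks -14.8 to -3.59; Fisher's exact test, two-sided p = 2.2e-11). The same difference was -9.76 points in the replicate 1 list (interval -15.4 to -3.84) and -17.2 points in the replicate 2 list (interval -24.0 to -9.84). In density, the central part and the arms of V held 73.5 and 36.3 regions per Mb, and those of X held 90.4 and 83.5.

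Some stretches were covered far more densely than the rest of the genome. On V, regions of the series list under 2 kb apart joined into a block from 4486612 to 4512470, 25.9 kb long, which held 8 regions covering 89.1% of it. Replicate 1 covered 79.8% of this block and replicate 2 covered 67.2%. It contains the widest region of each of the 3 lists, 13463 bp in the series list, 13251 bp in replicate 1 and 6608 bp in replicate 2. On II, a block from 6820950 to 6845307 held 19 regions covering 64.8%, with 60.3% covered in replicate 1 and 44.4% in replicate 2. On X, a block from 16343357 to 16380394, 37.0 kb long, held 30 regions covering 46.5%. Here replicate 2 covered more than replicate 1, 29.97% against 15.6%. For comparison, the median 20 kb window of the genome was covered to 1.51% in the series list and the 99th percentile (19.5% covered) lay below all 3 blocks. These blocks were chosen after the values were seen.

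**Figure D3:**
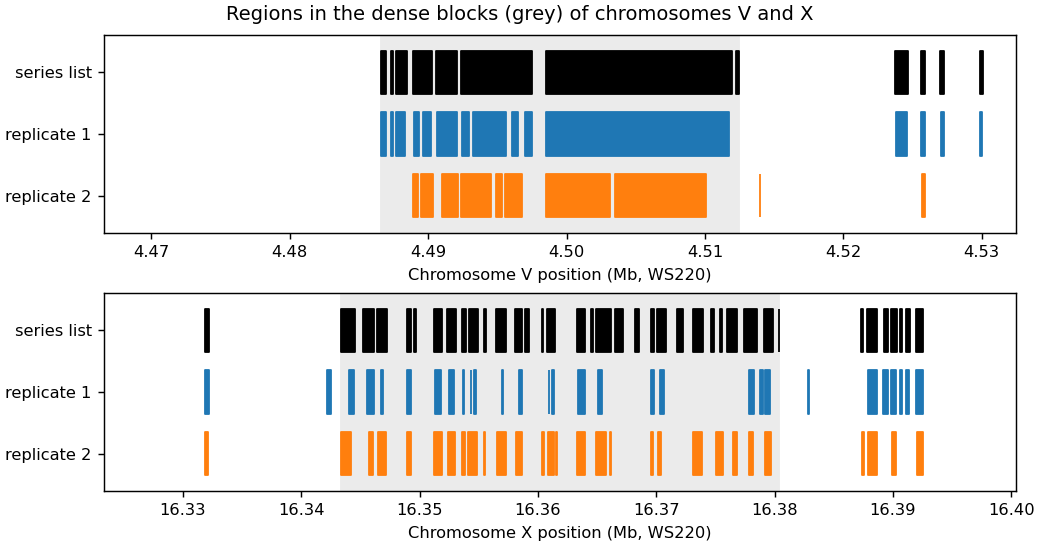
Positions (x axis, Mb on WS220) of regions in the 3 lists (rows) around the dense blocks of chromosomes V and X, with the blocks in grey; each bar is 1 region, to scale. The V block is covered to 89.1% in the series list, and in the X block replicate 2 (29.97%) covers more than replicate 1 (15.6%).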

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

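Of 98 values under alternatives, 89 were counted as kept. With the exception of the replicate 1 shares below, these kept their side of the threshold of the main test or stayed within their interval. Direction counted only where the main value had passed, so the X centre share was counted as kept when it fell below 50%. The alternatives that merged regions, resampled blocks, counted covered base pairs, measured lengths from the first region, shifted regions locally or held all lists to q-values under 0.001 were chosen after seeing the data. The overlap of replicate 2 with replicate 1 ranged from 77.4% with equal numbers of regions to 97.7% in the stronger 50% of each list, always above every random placement, including local shifts of 5 to 50 kb (chance 6.73% on average). The share of replicate 1 found in replicate 2 ranged from 33.02% with midpoints within 100 bp to 76.1% with equal numbers of regions, against 37.9%; equal list lengths bring both shares together by construction. Spearman's rho of the q-values stayed between 0.74 and 0.80 and Pearson's r between 0.86 and 0.93. The share of the series list found in both replicates moved from 36.7% to 31.6% with 50% reciprocal overlap, to 31.6% with midpoints within 100 bp, to 37.9% in the stronger 50% of each list and to 35.6% with q-values under 0.001, where regions found in neither replicate rose from 14.2% to 28.3%. Stricter matching or a shorter replicate 1 list accounts for the lower values by construction. Taking 1 replicate's list in place of the series list gave chromosome ratios of 1.02 to 1.104 on I, 1.08 to 1.099 on II (passing the exact test in both, unlike the main value, though both block intervals included 1) and 0.925 to 0.964 on IV, and with the replicate 2 list alone I and IV no longer passed. The cause was not tested. The ratio of III measured by covered base pairs was 1.12 with a block interval of 0.981 to 1.27, no longer past 1, and X (1.22) and I (1.15) then ranked above it. The cause was not tested. With regions under 2 kb apart merged, IV passed the exact test at 0.936, but its block interval of 0.859 to 1.014 included 1, unlike that of the main value. The 66.9% to 57.5% autosomal centre shares kept their call under all alternatives run, and that of X stayed short of it under all. The X share changed direction in the replicate 2 list alone (48.8%) and in the stronger 50% of the series list (48.8%), from 51.98% in the main test. No paired analysis was possible because the Input samples have no list here, so no group could be compared by replicate number. Not run for want of a genome or annotation on WS220 were the alternatives for gene features, gene lists, motifs and transgene loci, and the score had no second column to replace it. Depth is unknown, so how far it limits the replicate 2 list cannot be stated.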

Other observations

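The tests in this part were not among those fixed before the data were examined, and most were chosen after the results were seen. For the comparison of q-values within shared pairs, the expected outcome was written down before the test. The same holds for the q-values of single-replicate regions in the series list.

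Regions of the series list lay close together. The median distance between neighbouring midpoints was 5.26 kb, and 44.7% of regions had a neighbour within 2 kb. Moving each region at random within 50 kb gave 32.0% on average and 34.8% at most in 1000 placements, and uniform placement along the chromosomes gave 28.0% on average. Outside the V, II and X blocks, the most densely covered 20 kb windows began at II 4566001 (42.04% covered, 10 regions), X 12170001 (38.3%, 11 regions) and I 7698001 (35.3%, 8 regions). The strongest regions were found on every chromosome. X had 11.4% of its regions among the strongest 796 regions of the list, 10% of it, and the 5 autosomes had 8.8% to 10.6%, a difference that did not pass for any of the 6 chromosomes (Fisher's exact test, smallest adjusted p = 0.28 for X, raw p = 0.0467). The median width of X regions was 350 bp, against 295 to 311 bp on the autosomes.

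Replicate 1 listed 2.48 times as many regions as replicate 2. The looser q-value limit does not account for all of this, since with both lists under 0.001 the ratio was still 1.82. A lower statistical power in replicate 2, from depth or enrichment, is consistent with the smaller q-value of replicate 1 in 89.5% of shared pairs and with the concentration of single-replicate regions among the weak ones. Places bound in replicate 1 alone were examined for regions with q-values under 0.001 that replicate 2 lacked. Of the 2721 that the series list matched, 95.2% (exact 95% interval 94.3 to 95.96%) had a smaller q-value there. This goes against such places for most of them only if that list was called on the reads of both replicates and a replicate without binding would raise the q-value. The share was 97.6% over all 6736 matches with replicate 1, so it separates these regions little from the rest. The q-values also reflect depth and do not measure binding. How the series list was made is not stated, but its q-values followed replicate 2. Among regions with a −log10 q-value of 3 to 4 in replicate 1, the median rise in the series list was 4.19 for the 164 matched in replicate 2. It was 1.56 for the 1056 that were not. Binding in replicate 1 alone therefore stays open for all 2844 regions with q-values under 0.001 that replicate 2 lacked. They include 131 without a smaller q-value in the series list and 123 with no match there. Such binding stays open as well for weaker regions. Of the 4833 regions in replicate 1 only, 58.8% had q-values under 0.001, and the rest were not tested.

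Chromosome V carried fewer regions per Mb than any other. Uneven local density alone does not account for it, as the upper bound of the block interval was 0.787. The central 50% of V, at 73.5 regions per Mb, lay below that of the 5 others pooled (ratio 0.733, interval from resampled blocks 0.642 to 0.834). It also lay below each of I, II, III and X by more than the spread between blocks (ratios 0.614 to 0.813, highest upper 95% bound 0.945). For V against these chromosomes and against the pool, the values argue against sparse arms alone. Against IV, at 83.1, sparse arms alone stay open, as the gap was within the spread between blocks (ratio 0.885, interval 0.756 to 1.04). A different mappability or gene content of V was not tested, for want of the genome, and no biological explanation was tested.

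In the X block replicate 2 had the smaller q-value in 11 of 17 shared pairs (64.7%), against 55 of 611 on the rest of X (9.002%), and the block held 7 of the 162 regions found only in replicate 2. In the V block replicate 2 had the smaller q-value in 0 of 8 pairs, against 34 of 382 on the rest of V (8.9%), and in the II block in 1 of 17, against 51 of 483 on the rest of II (10.6%), so neither is shown to differ from its chromosome. The pairs of a block are neighbours that a single local event would move together, and the X block was chosen after its values were seen, so no p-value is given. A candidate explanation for the X block is a higher local DNA content in the replicate 2 material that its input did not offset, which cannot be told apart from stronger binding there without the reads. For the V block, extra copies of unc-62 from the transgene may contribute, as unc-62 is on chromosome V too. The widest region lay on V in each of the 3 lists, but at the same locus, so this is the 1 observation that prompted the explanation and no test of it. Whether the block covers the gene was not tested, because the gene table is on another assembly.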
